A study of Canis lupus familiaris with 50 samples.

How the data were processed

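Tumour DNA from lymph nodes was labelled with cyanine-5 (red) and skin DNA of the same dog with cyanine-3 (green), per the labels, and both were hybridised to an oligonucleotide array of the dog genome. No dye swaps were made. The labels give 50 samples of 1 group, numbered 1 to 50 as replicates, each a separate tumour. The files hold 180880 spots per array, of which 6946 are controls. The 173934 other spots hold 171534 probes, and 171050 of these have a position on chromosomes 1 to 38 or X in CanFam3.1, the build the file headers give. The median spacing of probes is 12.7 kb.

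The processed red and green signals are intensities on a linear scale that Feature Extraction made, per the file headers, by subtracting background, removing spatial trends and scaling the dyes linearly. Version 11.5.1.1 was used for 47 arrays and 10.1.1.1 for 3, per the file headers. The deposited files also hold spot and background intensities and a log10 ratio of red over green, which was used only to check the direction. A deposited value table holds log2 ratios of tumour over skin. It correlated with the scanner log2 ratios at 0.910 to 1.000 per array, and its column medians lay between -0.02 and 0.05. The correction behind it is not given in the sources used here. It was used in the part held here, 98647 probes (57.7%), as an alternative.

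The log2 ratio of the processed red over green signal was centred on each array's median over autosomal probes, with no loess or quantile step. Control spots and outlier-flagged spots were left out, and spots of 1 probe were averaged. Each chromosome was divided by a penalised least-squares search with a penalty of 5 times the noise variance times the natural log of the number of probes, and at least 5 probes per segment. A segment median of 0.2 or more was a gain and of -0.2 or less a loss. A bin of 1 Mb with at least 10 probes took the call of most of its probes.

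Recurrent bins were found by shifting each tumour's calls around the genome 10000 times and taking the largest count of each shift, at a family-wise p under 0.05. A whole-chromosome event needed 70% of the probes of a chromosome. Bin and chromosome medians were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept and eBayes, Benjamini-Hochberg adjusted p under 0.05 and, for bins, a mean of at least 0.1 in size). Gained and lost shares were compared with 100000 sign flips. Fisher's exact test served for pairs of events. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and pandas 2.3.3 did the rest. P-values of limma and of the sign flips measure the spread between tumours. Those of recurrent bins and whole chromosomes set the counts against random placement of each tumour's own calls.

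The search was tested on simulated data, and all 6 planted events were found as recurrent regions with 0 false regions. A 1.0 Mb loss planted in 12 tumours was called in 11. The simulated noise was independent between probes and arrays, so the 0 false regions do not cover trends shared by the arrays. In the limma test on 2339 simulated bins, a shift of 0.2 was recovered in 100% of 100 bins and a shift of 0.1 in 47%, with 0 false calls. The limit on the mean equals a shift of 0.1, and by the adjusted p alone 92% of these were recovered. The bins too were drawn independently. No pair of arrays held the same tumour by its segments: the highest correlation of segment profiles, 0.921 between replicates 29 and 41, joined tumours that differed in the gain of chromosome 13.

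Several parts of the plan were changed. The files name no genes, and the gene table used here is of another build (UU_Cfam_GSD_1.0), so only its names, chromosomes and gene order were used. Gene list members were therefore read by chromosome instead of by their nearest probes, genes in peak bins were not named, and the antigen receptor loci were not analysed here. The background alternative used the median spot signal. The rule for named genes, fixed before the data were examined, took up to 6 members per list on events of 10 or more tumours and 1 or 2 with the fewest, and the peak bin of each of the 10 most frequent regions. Chromosome 27 and X list members were named after their values were seen. The values of 1 list member are not reported here.

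Alternatives, whose effect the closing section gives, covered the background, normalization, centring, flags, dim and noisy data, call threshold, penalty, bin size, event length, share of a chromosome, the value table and slide as a block. Those added after seeing the data were the arrays of the first scan year left out (5 arrays), the scanner values on only the probes of the value table, and scan day as a block.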

Results

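Copy number was measured in 50 canine diffuse large B-cell lymphomas, tumours of B cells sampled from lymph nodes of dogs. Each array set the DNA of 1 tumour against skin DNA from the same dog, so a copy number difference that a dog carries in all of its cells cancels in the ratio. All 50 samples formed 1 group, and every comparison was of tumour against skin within a dog. The 50 arrays lay on 18 slides and were scanned on 10 days. The median spot signal of an array ranged from 72.0 to 848.5 in the tumour channel and from 78.0 to 460.0 in the skin channel, and 88.6% to 99.8% of probes were well above background. Probe noise, as the SD of neighbouring probes on the log2 scale, ranged from 0.155 to 0.630 between arrays. The number of arrays limits the precision of each share of tumours, and exact binomial 95% confidence intervals are given for the main events.

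Gain of the whole of chromosome 13 was the most frequent whole-chromosome event. It was present in 22 of 50 tumours (44%, 95% confidence interval 30.0% to 58.7%), and no tumour had lost it. Chromosome 13 carries MYC, a transcription factor that drives cell growth, the receptor tyrosine kinases KIT, PDGFRA and KDR, and the kinase PTK2. Its median log2 ratio averaged 0.20 ± 0.24 (SD, n = 50), and in the tumours with the gain it lay between 0.27 and 0.94. Gain of chromosome 31, which carries the transcription factor RUNX1, was present in 12 of 50 tumours (24%, 95% confidence interval 13.1% to 38.2%), with a mean log2 ratio of 0.10 ± 0.21 (SD, n = 50). Loss of chromosome 14, which carries the telomere protein gene POT1, was present in 10 of 50 tumours (20%, 95% confidence interval 10.0% to 33.7%), with a mean of -0.13 ± 0.28 (SD, n = 50). Chromosome X was lost over 70% or more of its probes in 6 of 50 tumours (12%).

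Whole-chromosome counts were set against 10000 draws that placed each tumour's own calls on other chromosomes. The gains of 13 and 31 and the loss of 14 each had an adjusted permutation p of 0.0001, the smallest these draws can give, and the loss of X had an adjusted permutation p of 0.0009. Gain of chromosome 27, which carries KMT2D and CCND2, was present whole in 4 tumours and did not pass (adjusted permutation p = 0.96). The other whole-chromosome gains were found in 1 or 2 tumours per chromosome, over 17 chromosomes. A tumour had at most 6 whole-chromosome events, and 9 tumours had none.

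**Figure D1:**
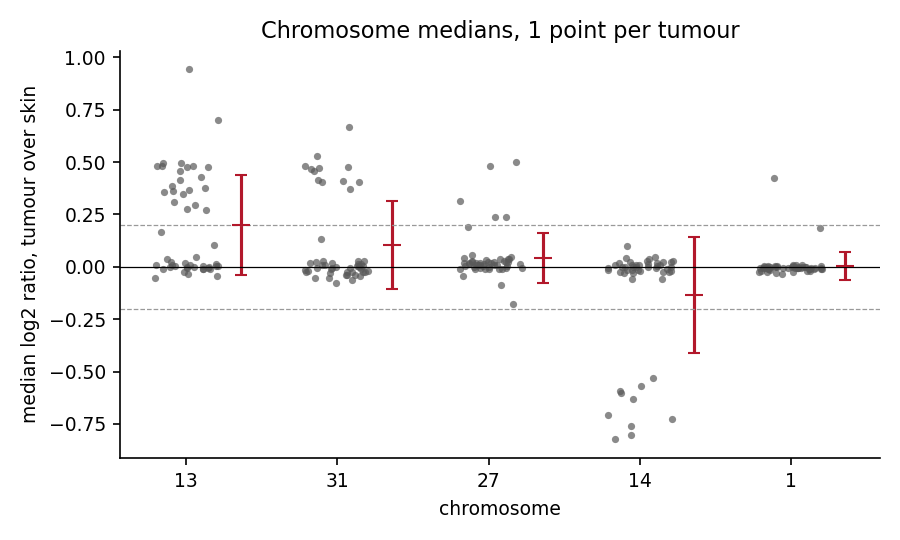
Median log2 ratio of tumour over skin for chromosomes 13, 31, 27, 14 and 1 (y axis), with 1 grey point per tumour, the red bar giving the mean and SD over 50 tumours and the dashed lines the call thresholds of 0.2 in size. On chromosome 13 the gained tumours lie between 0.27 and 0.94, and chromosome 1 is shown as a chromosome gained whole in 1 tumour.

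Of the 2339 bins of 1 Mb, 106 were gained in more tumours than chance placement along the genome gave, in 4 regions, and 105 were lost, in 18 regions. Of these loss regions, 5 passed under each of 12 alternatives that held probes there, those on chromosomes 8, 14, 26 and 28 and at the start of X. The number of loss regions fell to 8 at a call threshold of 0.3, and to 8 with normexp background while the lost bins rose to 199. In the deposited value table, which holds 57.7% of the probes and none of X, it was 5, and 8 in the scanner values on the same probes. At least 8 tumours were needed to pass in either direction. The gained bins covered chromosome 13 throughout, with a peak at 24000001 to 25000000 (CanFam3.1) in 23 of 50 tumours. They also covered chromosome 31 throughout, where every bin was gained in 12 of 50 tumours. The count had no peak there, and the bin at 18000001 to 19000000 only had the largest mean. Chromosome 14 was lost throughout, with a peak at 5000001 to 6000000 in 11 of 50. The interval gained in all 23 of those tumours ran from 24494931 to 26256894 on chromosome 13 and held 122 probes. A further 2 gained regions lay on chromosome 27, at 4000001 to 5000000 and 16000001 to 18000000, each in 8 of 50 tumours with an adjusted permutation p of 0.049. Under 12 alternatives in processing and calling, the first passed in 3 and the second in 6.

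The most frequent loss lay on chromosome 26 at 25000001 to 28000000, with its peak at 27000001 to 28000000 in 38 of 50 tumours (76%, 95% confidence interval 61.8% to 86.9%). The mean log2 ratio of the peak was -0.59 ± 0.46 (SD, n = 50), its lowest value was -1.80, and no tumour had gained it. At the probe level, 42 of 50 tumours had lost the 15 probes from 27362010 to 27587225. When only probes well above background on every array were kept, 43 of the 83 probes of the peak remained and the count fell to 2 tumours. This filter acts on the tumour signal, which a loss lowers, so its count is no independent measure of the loss. Of the 40 probes left out, 30 were dim in the tumour channel only, 10 in both channels and 0 in the skin channel only. Over the arrays they had 472 dim values in the tumour channel and 228 in the skin channel. Of the 472, 389 lay in the 38 tumours called lost and 83 in the 12 not called, so some were dim without a called loss. In the gained peak of chromosome 13 the filter left 59 of 64 probes, with 5 of the 5 left out dim in the tumour channel only. In the value table the peak was lost in 45 tumours, and in 46 in the scanner values on the same probes. A further loss lay at the end of chromosome 8, from 73000001 to 74320310. Its peak bin, 73000001 to 74000000, was lost in 17 of 50 tumours (34%, 95% confidence interval 21.2% to 48.8%). The mean of that peak was -0.41 ± 0.61 (SD, n = 50), and 4 tumours had gained it. At the start of the region, the 28 neighbouring probes from 72994213 to 73362218 each lay in a lost segment in 30 to 37 of 50 tumours.

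**Figure D2:**
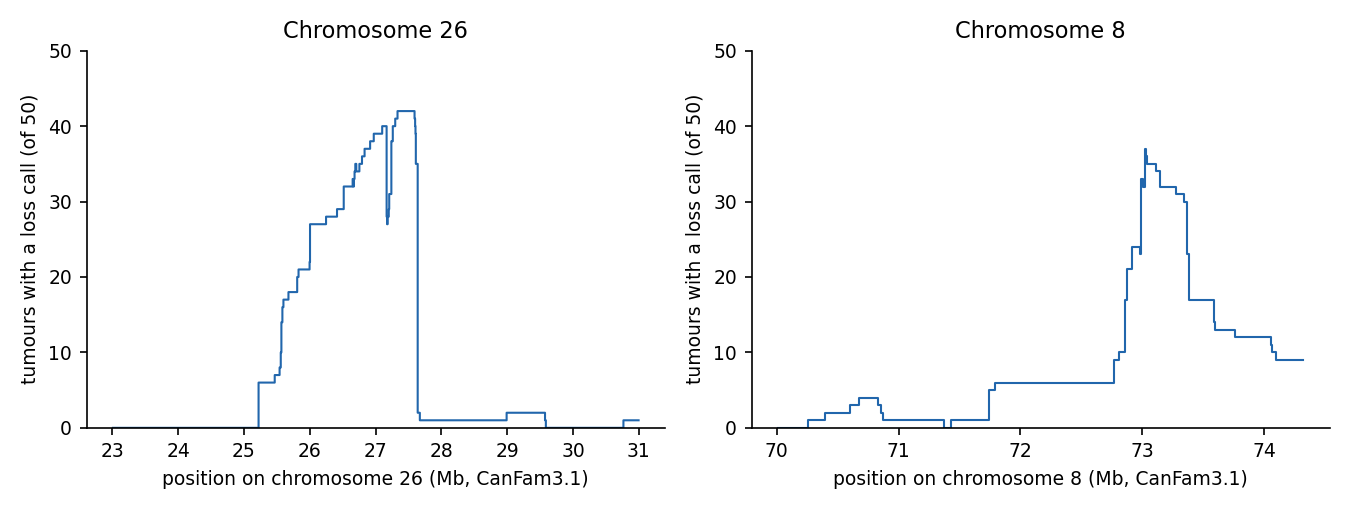
Number of tumours, of 50, with a loss call at each probe (y axis) along parts of chromosomes 26 and 8 (x axis, Mb in CanFam3.1). The count reaches 42 tumours on chromosome 26 and 37 on chromosome 8.

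The first bins of chromosome X, from 1 to 7000000, were lost in up to 21 of 50 tumours (42%, 95% confidence interval 28.2% to 56.8%), with a mean log2 ratio of -0.30 ± 0.30 (SD, n = 50) in the peak bin. The bin from 3 to 4 Mb was lost in 13 of 50 tumours. In 10 of these 13 a segment ended between 6 and 7 Mb, at positions from 6030759 to 6659679. The rest of X, beyond 7 Mb, was called lost in 4 of the 13, gained in 1 and neither in 8. The other 4 recurrent loss regions of X were present in 8 tumours each. A further 10 regions on chromosomes 9, 17, 18, 20, 24, 25, 28, 34 and 37 were 0.625 to 3.12 Mb long, and their peak bins were lost in 8 to 19 tumours. The most frequent of these lay at 55000001 to 58122292 on chromosome 20 and at 39000001 to 41154679 on chromosome 28. On 20 the peak bin, 58000001 to 58122292, held only 10 probes and was lost in 19 of 50 tumours, and the fewest in a bin of the region was 9. On 28 the peak bin, 40000001 to 41000000, was lost in 18 of 50, and the fewest was 15. The regions next in frequency peaked at 50000001 to 51000000 on chromosome 9, in 11 of 50 tumours, and at 1000001 to 2000000 on chromosome 17, in 10 of 50. The calls of these small regions depended on the processing. The deposited value table was set against the scanner values on the same probes. There the loss was called in 8 against 21 tumours on chromosome 28 and in 2 against 11 on 9. It was called in 2 against 10 on 17 and in 3 against 7 on 37. On chromosome 25 it was called in 21 against 32, but this rests on 13 of the 39 probes of the peak. Over all its probes that peak was called lost in 8 of 50 tumours. The peak bin on chromosome 20 fell to 10 tumours at a call threshold of 0.3.

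**Figure D3:**
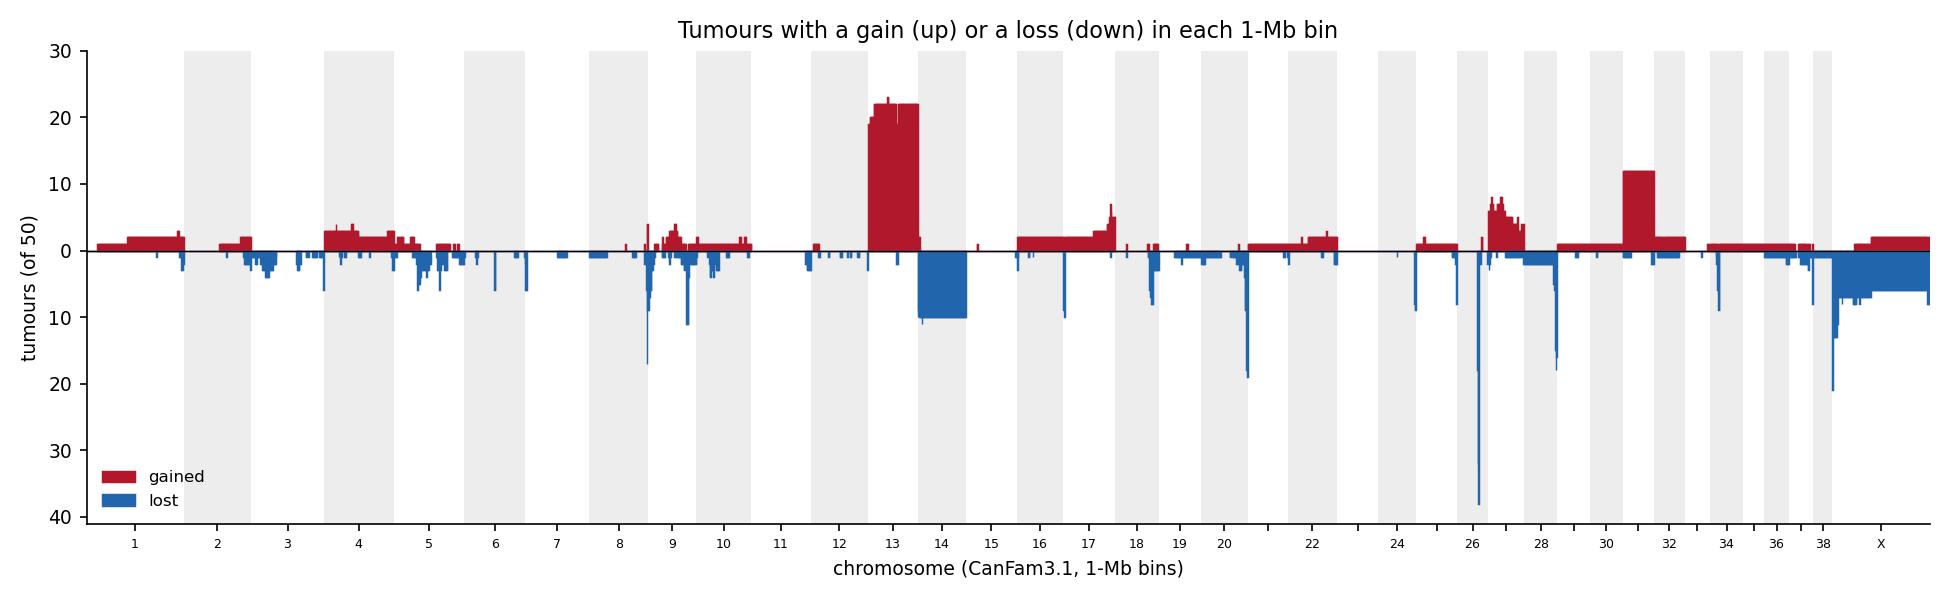
Number of tumours, of 50, with a gain (red, upward) or a loss (blue, downward) in each 1-Mb bin along chromosomes 1 to 38 and X. Gains reach 23 tumours on chromosome 13 and losses reach 38 on chromosome 26.

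A test that did not rest on calls set the mean log2 ratio of each bin against 0 with limma. It found 104 bins above 0 and 136 below 0 at a mean of 0.1 or more in size. With normexp background there were 85 above and 90 below, 87 and 82 in the value table, and 90 and 97 in the scanner values on its probes. Of those above, 63 lay on chromosome 13, 22 on chromosome 31 and 6 on chromosome 27. Of those below, 51 lay on chromosome 14 and 26 on X. By the adjusted p alone, 643 bins were above and 697 below, most of them with means under 0.1. No dyes were swapped, so a probe bias common to all arrays is part of these means. With the segments removed, the probe values of 2 arrays still correlated across probes at a median r of 0.351 over the 1225 pairs of arrays.

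On average 3.19% ± 3.07 (SD, n = 50) of probes were gained in a tumour and 2.36% ± 2.66 (SD, n = 50) were lost. The difference of 0.828 percentage points was smaller than its spread (SD 3.52) and did not pass a two-sided sign-flip permutation test (p = 0.10). The call changed under 5 alternatives, with a difference of 1.03 to 3.215 points and p between 1e-05 and 0.043 in the same permutation test, the largest being that of the value table, and 2.64 points in the scanner values on its probes. The gained share was the larger in 30 tumours and the lost share in 20.

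For pairs of recurrent regions on different chromosomes, 29 of 219 were found together more often than chance by Fisher's exact test with Benjamini-Hochberg adjustment, and 0 less often. All 29 pairs were between the 10 small loss regions named above, and 0 included a gain. The number of pairs fell to 4 with normexp background, to 9 with the segmentation penalty doubled, to 1 at a call threshold of 0.3 and to 0 in the value table. A set of 6 events (the whole-chromosome gains of 13 and 31 and loss of 14, and the losses on 26, 8 and the start of X), which leaves out the small loss regions, was tested among itself in 15 pairs, a comparison chosen after the values were seen. None passed in Fisher's exact test (lowest adjusted p = 0.74). Gains of 13 and 31 were found together in 5 tumours, where 5.28 were expected.

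**Figure D4:**
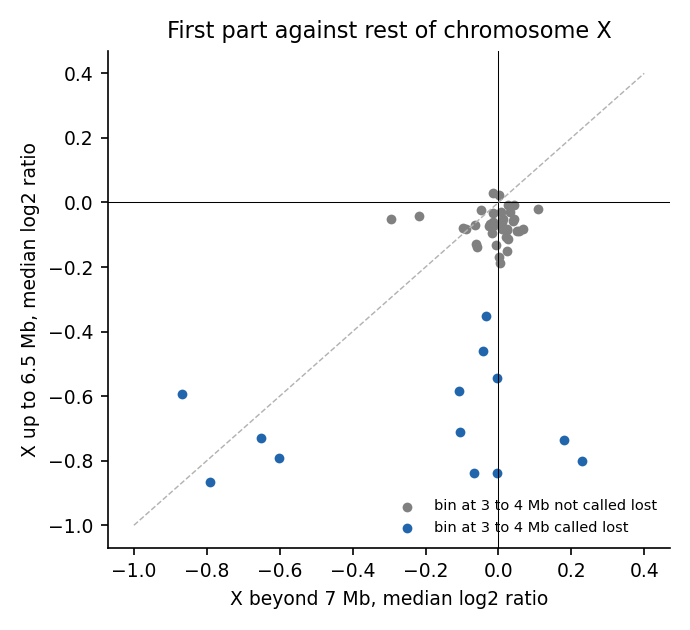
Median log2 ratio of chromosome X up to 6.5 Mb (y axis) against that beyond 7 Mb (x axis), 1 point per tumour, with tumours whose bin at 3 to 4 Mb was called lost in blue and equality as a dashed line. The 13 blue points lie between -0.87 and -0.35 on the y axis.

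The 6 gene lists fixed in advance were read at the level of whole chromosomes, since the files name no genes, and 90 of 91 list entries could be given a chromosome. Of the 19 oncogenes and cell cycle genes, 9 lay on a chromosome gained in 10 or more tumours, among them MYC, KIT, PDGFRA, KDR, PTK2 and RUNX1, and 1 lay on chromosome 14. The 9 all lay on chromosomes 13 and 31, which hold 4571 and 2730 of the 171050 probes. Members on the same chromosome share its value, so they are not separate events, and no enrichment of a list was tested. CCND3, a cyclin on chromosome 12, was on a chromosome with 0 whole gains and 0 whole losses. Of the 15 tumour suppressors, POT1 alone lay on a chromosome lost whole in 10 or more tumours, while CDKN2A, an inhibitor of the cell cycle on chromosome 11, lay on a chromosome with 0 whole losses. Without the 5 arrays of the first scan year, chromosomes 14 and 31 each changed whole in 9 of 45 tumours, so POT1 and RUNX1 fell under the limit of 10, and the list members above it fell from 11 to 5. In the B-cell receptor and NF-kB, B-cell transcription factor, chromatin and antigen presentation lists, none of the members given a chromosome lay on such a chromosome. With 6 whole losses, chromosome X, which carries BTK, a kinase of B-cell receptor signalling, and the histone demethylase KDM6A, was the nearest.

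In limma on chromosome medians, 11 list entries lay on chromosomes with a mean above 0 (13, 31 and 27) and 23 on chromosomes with a mean below 0. Against these 34 entries in all, 11 passed limma in the value table and 23 in the scanner values on its probes. Adjusted over the list alone, the counts were 11 and 24. The means below 0 ranged from -0.01 to -0.13, and of these chromosomes only 14 passed 0.1 in size. The others, 5, 6, 18, 20 and 26, were each lost whole in 0 tumours, and their means lay between -0.026 and -0.007. A bias or trend shared by the arrays is part of such small means, so the entries there do not show a loss. A chromosome value says nothing of a focal change at a gene on it.

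Slide and scan day were tested as batches. Their share of the variance between arrays was tested for 7 measures by permutation, and the lowest adjusted p of the 14 tests was 0.20. Before adjustment, the mean of the small loss regions had a permutation p of 0.04 by slide and 0.042 by scan day. Slide took 52.7% of its variance and scan day 33.6%. Chromosome 13 had a permutation p of 0.026 by scan day (36.0%), and in all other tests the permutation p was 0.13 or more. By scan day, the mean log2 ratio of chromosome 13 was above 0 on 9 of 10 days, that of 31 on 9 and that of the focal loss on 26 below 0 on 10. With the slide as a random block, limma found 104 bins above 0 and 135 below.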

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

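The whole-chromosome result, 4 events past the threshold, stayed at 3 or 4 under all 14 alternatives, and under the 12 that kept the 70% rule whole gains of 13 and 31 and whole losses of 14 numbered 18 to 23, 9 to 12 and 9 to 10. Of 163 values of single regions and chromosomes under alternatives, 154 stayed within their spread, 9 moved and 0 reversed. Most of these results are counts of tumours, which cannot reverse. The spread allowed was wide: on chromosome 24 from 47 Mb, lost in 9 tumours, all 10 values stayed though they ranged from 5 to 12. The number of recurrently gained bins was 213 with 0.5 Mb bins, 53 with 2 Mb bins and 5 with only calls shorter than 10 Mb, which leave out whole chromosomes by construction. Recurrently lost bins numbered 199 with normexp background, 185 with loess, 202 and 52 with 0.5 and 2 Mb bins, and 42 with only short calls. Bins with a mean above 0 numbered 245 and 49 with the 0.5 and 2 Mb bins and 304 at a mean of 0.05, and those below 0 numbered 317, 55 and 409, with 90 under normexp and 82 in the value table (97 in the scanner values on its probes). Recurrent loss regions numbered 12 without the noisiest arrays, 11 with loess, 14 with only bright probes and 10 with the penalty doubled. Bin counts follow bin size by construction, and for normexp and loess the cause was not tested.

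The gained minus lost share passed in the sign-flip permutation test at a threshold of 0.3 (1.07 points, p = 0.015), with the penalty doubled (1.03, p = 0.043), with only bright probes (1.07, p = 0.033), in the value table (3.215, p = 1e-05) and in the scanner values on its probes (2.64, p = 0.0001). The last alternative was chosen after seeing the data, and the other p-values ranged up to 0.52. The value table covers part of the genome, so its share is not of the whole. Pairs found together numbered 19 without the 3 noisiest arrays, 4 with normexp, 12 with loess, 1 at a threshold of 0.3, 9 with the penalty doubled, 0 in the value table and 5 in the scanner values on its probes, and the cause was not tested. Gene list entries past limma numbered 11 in the value table and 23 in the scanner values on its probes, so that its coverage leaves a part of the fall open, and those on chromosomes changed in 10 or more tumours numbered 5 without the 5 arrays of the first scan year, where fewer tumours were counted.

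No paired analysis was possible because there is 1 group, so no 2 groups share replicate numbers, and the tumour and skin of a dog are already set against each other in every ratio. The correction for GC content was not run, since no sequence of this build was at hand. The alternatives for probes per gene, flanks and block means belong to results that could not be computed as planned. Signal over background limits arrays with tumour medians as low as 72.0.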

Other observations

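Of the tests below, those of an inherited variant, of mixed-up pairs and of a lost chromosome Y were chosen only after the result was seen. The antigen receptor test was narrowed and the conditions of the inherited variant, pair and Y tests were settled again after first values were seen.

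By the calls of the 1-Mb peak bins, loss on chromosome 26, chromosome 8 or both was present in 43 of 50 tumours, and both in 12. At single probes the highest counts were 42 of 50 tumours on 26 and 37 of 50 on 8, so by that measure more tumours had both. The depth of the loss on 26 was not correlated with that on 8 across tumours (Pearson r = 0.04, permutation p = 0.77, Spearman rho = 0.06, permutation p = 0.66, and r = 0.03 without the 2 farthest tumours). Of 4 relations computed, that of the start of X with the largest whole-chromosome change was the closest to the threshold (r = -0.26, permutation p = 0.063, adjusted p = 0.19, rho = -0.27, permutation p = 0.058, adjusted p = 0.22, and r = -0.21 without the 2 farthest). In 2 tumours, replicates 32 and 36, X beyond 7 Mb was at -0.29 and -0.22 while its first part was at -0.05 and -0.04.

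The small losses shared by many arrays may be a wave in the log ratios. Across 50 arrays, 9 such regions on 8 chromosomes named before this test rose and fell together, with a median pairwise r of 0.576 (range -0.09 to 0.96), and with the region on 34 it was 0.570. In the value table, the tumours called lost at 5 of the regions came to 44.4% of those in the scanner values on the same probes, and to 30.6% over the 4 regions with most of their probes in it. They were noted as losses at chromosome ends, but 7 of the 9 lie there. Slide took 52.7% of the variance of the mean of the small loss regions and scan day 33.6%. The permutation p was 0.04 and 0.042, and neither passed after adjustment (adjusted p = 0.20). Losses that occur together in the tumours would give such an r too, and no biological explanation was tested, so that stays open.

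For the focal losses on 26 and 8 the tables argue against the same wave, with a median r of -0.0495 with those regions. For the loss on 26 they also argue against an inherited variant, which cancels against skin of the same dog and in mixed-up pairs would give gains as often as losses: 38 losses against 0 gains, 100% with an exact 95% confidence interval from 90.75%. On 8 an inherited variant would cancel in matched pairs too, so only mixed-up pairs are at issue there. The 17 losses against 4 gains, 81%, leave an interval of 58.09% to 94.55%, so this share does not settle it. By the X values given below, 0 of 50 tumours looked like a pair of different sex, while mixed-up pairs of the same sex were not tested. A candidate explanation is the rearrangement of antigen receptor genes in the tumour cells: the gene table puts 39 V and 5 C genes on chromosome 26 and 71 V or C genes among the last 100 genes of chromosome 8. This stays open. The chromosomes 26 and 8 prompted the idea, so 16, 17 and 18, other chromosomes with V genes, were taken to test it. Focal losses there were not shown to be more frequent than elsewhere (one-sided exact permutation p = 0.291). The test took the most frequent focal loss anywhere on a chromosome and did not tell receptor genes of B cells from those of T cells. It therefore cannot decide the question. Chromosome 5, with 1 V gene, was left out. Of the 3, 17 has 0 C genes in the gene table and its loss is one of the small regions above, and 16 and 18 alone gave p = 0.49 in the same exact permutation test. Outside the receptor chromosomes, the loss on 20 was as frequent as that on 8 in 1-Mb bins with calls shorter than 10 Mb, each in 17 tumours. At single probes of the 2 regions, with calls of any length, the highest counts were 20 tumours on 20 and 37 on 8.

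For the losses at the start of X, a median r of 0.159 argues against a shared wave in the 13 tumours with a called first part. Their first part lay between -0.87 and -0.35. The peak bin was called lost in 21 tumours, with values up to -0.175. Tumours without a called first part ranged from -0.19 (replicate 22) to 0.03 (replicate 45), most of them below 0. The r rests on the deep losses. It cannot tell whether a small shared shift added calls in the peak bin or lowered its mean of -0.30. Mixed-up pairs of dogs of different sex are argued against too: 0 of 50 tumours had the rest of X at 0.75 or more in size with a first part near 0. Of the 13 tumours, 2 had the rest of X at that size. They were picked by a lost first part, which such a pair would not have, so their count cannot test this. Loss of chromosome Y, which shares the first part of X, may account for some: in 61.5% of the 13 (8 tumours, exact 95% confidence interval 31.6% to 86.1%) a segment ended between 6 and 7 Mb and the rest was not lost. Asking also that the rest was not gained gives 53.8%, under the 60% set for this test, so 1 tumour decides it. The sex of the dogs was not used here.

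Exchanging tumour and skin at random within arrays, 1 of 100 exchanges, the real one, gave as many as 104 bins above 0, and the highest of the others was 0. The same held for the 136 bins below 0, again 1 of 100 with 0 as the highest other, so that chance exchange can be excluded for both. No dyes were swapped, and a probe bias common to all arrays would give the same outcome. The exchanges therefore cannot exclude such a bias.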
